A study of Mus musculus with 9 samples.

How the data were processed

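RNA was measured on 9 Affymetrix Mouse Gene 1.0 ST arrays of sorted mouse CD4 T cells. Per the labels, mice were sensitised with 3 intraperitoneal injections of 10 µg ovalbumin in 1.5 mg aluminium hydroxide at days 1, 14 and 21. They then breathed 1% ovalbumin aerosol on 3 days in a row (acute) or over 12 weeks (chronic). Sham-treated mice gave the naive cells. Cells were sorted by CD4, CD44, CD69 and further surface markers given in the labels, and stimulated with anti-CD3 and anti-CD28 for 8 h before RNA extraction. The 3 groups are naive (spleen, day 29), early Th2 (lung, acute, day 29) and stable Th2 (lung, chronic, day 104), each with 3 arrays. Groups were taken from the titles, and no array was left out. The series asks, in the words of its labels put briefly, what keeps chronic allergic inflammation going.

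The deposited table holds 1 log2 intensity per probe set and array, normalised across the 9 arrays by the authors with RMA, as the submitters' processing notes name it. They also name limma. Versions, the genome build, the probe annotation and any filter are not given in the sources used here. The values were used as they are, without further normalisation. Of 34760 probe sets, 22961 are listed with a gene, 21640 of them with 1 gene and 1321 with several, and 11799 are not listed with a gene. Probe sets that name several genes were not used. A gene was represented by the probe set with the highest mean over all arrays among those that name it alone, which gave 19937 genes. Entrez identifiers were matched to a mouse gene table for 21553 probe sets, and 0 symbols had to be updated. Positions on the genome are not analysed here. Detection calls and scan dates are not used here. No filter removed dim genes. As a measure of background, the 1015 olfactory receptor genes (symbols of Olfr followed by a number) were used, a choice made after seeing the data.

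Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided) on all 9 arrays, with the 3 groups as the only term. The 3 comparisons are early Th2 minus naive, stable Th2 minus naive and stable Th2 minus early Th2. P values were adjusted by Benjamini and Hochberg over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Differences are on the log2 scale, SE is the standard error of the moderated test, and SD is that of the 3 arrays of a group. The comparison of both Th2 groups is also the test of whether the comparisons with naive cells differ. With 3 arrays against 3, an exact permutation of labels cannot give a two-sided p under 0.1, so that none is given.

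Fixed before the data were examined were the groups, the tests, the rule for named genes, 36 gene lists with 626 symbols, and all alternatives except those named below as chosen later. The lists are sort markers, Th2 lineage and cytokines, Th1 and cytotoxic, Th17, Treg, Tfh, naive and lymph node homing, tissue residency, costimulatory and inhibitory receptors, T cell receptor induced early genes, cell cycle, survival and apoptosis, glycolysis, fatty acid uptake and oxidation, cholesterol synthesis, TGF-beta signalling, Notch signalling, type I interferon response, chemokine receptors and integrins, unfolded protein response and secretion, ribosomal proteins, microRNA machinery, dissociation stress, sex-linked, B cell, CD8 T cell, NK cell, ILC2, macrophage and monocyte, dendritic cell, eosinophil, neutrophil, mast cell and basophil, lung epithelium, endothelium and stroma, and erythroid and platelet. Of the 626 symbols, 64 are not analysed here. Lists with 5 or more measured genes, 33 in number, were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 33 lists, and again with the correlation estimated for each list. The roast variant fry was run beside it, and it tests whether the genes of a list move, on balance, 1 way, without comparing them with other genes. Members of a list past the threshold were counted over all genes and adjusted over the list alone. Lists share members, so that their results are not independent.

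Named per comparison were the 8 genes with the largest rise and the 8 with the largest fall among called genes whose arrays do not overlap between the groups. Predicted genes and immunoglobulin or T cell receptor segments were left out. To these come up to 4 called members of each list with the largest difference, or up to 2 members as values where none was called, and in every comparison the sort markers with Gata3, Il4, Il5, Il13, Foxp3 and Tbx21. The text prints a selection of these genes. Il2 on single arrays, Mir155, Mir31, Mir505, Mir7-1, Mir701, Kcnma1, Bex4 and Aqp9 were chosen after their values were seen.

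The overlap of calls against naive cells was set beside 20 simulations of unchanged groups that share the naive arrays and beside the overlap of independent lists. The same simulations gave the share of genes with opposite signs for the direction of the changes between the Th2 groups, whose interval is an exact Clopper-Pearson interval at 95%.

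Alternatives planned in advance were median centring, quantile normalization, a filter on genes under the lower quartile or the median level, the mean of all probe sets of a gene, all probe sets, a 2-fold threshold, trended and robust moderation, array weights, a fit of only the groups compared, the replicate number as a block, each array left out in turn, the estimated correlation, and fry. Chosen after seeing the data were cyclic loess normalization and leaving out both naive 1 and stable Th2 3. The closing section gives their effect. Every split of the 6 arrays of a comparison into 3 and 3, 10 in number, was fitted as well. For tests of shifts with level, 10000 random lists matched to a list in 50 bins of mean level were drawn.

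The pipeline was tested on simulated data with the spread of these arrays, in 5 draws with 200 changed genes among 19937. For early Th2 minus naive, 26.3% of genes changed by 0.5, 74.6% of those changed by 1 and 96.4% of those changed by 2 on the log2 scale were called. For stable Th2 minus early Th2 the shares were 24.8%, 69.6% and 93.9%, and for stable Th2 minus naive 23.9%, 73.4% and 95.5%. A list of 30 genes shifted by 0.5 was found in 5 of 5 draws of each comparison. Unchanged genes were called 36, 43 and 34 times in total for early Th2 minus naive, stable Th2 minus naive and stable Th2 minus early Th2. Unchanged lists were called 0, 0 and 1 times. Noise was drawn independently for each gene, with the same spread in all groups. These shares and counts thus do not cover genes that vary together, arrays that stand apart or shifts of whole arrays. An array gives no count of molecules, so that no depth or counting interval applies and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.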

Results

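Gene expression was measured on 9 Affymetrix Mouse Gene 1.0 ST arrays, 3 for each of 3 groups of sorted mouse CD4 T cells. Naive CD4 T cells, negative for CD44, came from the spleen of sham-treated mice at day 29. Early Th2 cells, positive for CD69, came from the lung in acute ovalbumin-induced airway inflammation, also at day 29. Stable Th2 cells came from the lung at day 104, after 12 weeks of chronic inflammation. All cells were stimulated for 8 h through CD3 and CD28 after the sort, by the labels, so that every level below was measured after that step. The values are deposited log2 intensities, and 19937 genes were tested. Whether the 3 replicates of a group came from separate animals is not given in the sources used here, so that each p measures the spread between samples. Tissue changes together with cell state in both comparisons with naive cells, and day changes together with stage in the comparison of both Th2 groups. Day also changes in the comparison of stable Th2 cells (day 104) with naive cells (day 29). The number of arrays limits the precision.

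The naive arrays were separated from the Th2 arrays. The first principal component held 51.8% of the variance and set the 3 naive arrays apart from the 6 Th2 arrays, among which early and stable Th2 arrays overlapped. Stable Th2 replicate 3 had a Pearson correlation of 0.991 with early Th2 replicate 3, above those of 0.980 and 0.985 with stable Th2 replicates 1 and 2. Pearson correlations across genes within a group ran from 0.987 to 0.996 in early Th2 cells, from 0.980 to 0.990 in stable Th2 cells and from 0.939 to 0.991 in naive cells. Naive replicate 1 stood apart from both other naive arrays. Il2, the T cell growth factor made after stimulation, had a level of 5.07 in naive replicate 1, against 11.33 and 11.27 in naive replicates 2 and 3. The T cell receptor induced early genes list had a median level of 8.40 on that array, against 10.21 and 10.42. The naive and lymph node homing list had a median level of 10.35 on it, against 8.87 and 8.80. Olfactory receptor genes, which T cells are not known to use and which serve here as a measure of background, had a median level between 4.94 and 5.21 on the naive and early Th2 arrays. Their median was 5.67, 5.51 and 5.15 on stable Th2 replicates 1, 2 and 3.

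Early Th2 cells were compared with naive cells to see which genes distinguish lung T cells of acute inflammation from T cells that have not met antigen. Cytokine genes of type 2 immunity rose. Il5, which drives eosinophil growth, had a level of 12.65 ± 0.07 (SD, n = 3) in early Th2 cells and 5.15 ± 0.15 (SD, n = 3) in naive cells (adjusted p = 5.21e-09). Il13, which acts on airway epithelium and smooth muscle, rose from 6.33 ± 0.27 to 13.06 ± 0.04 (SD, n = 3 each; adjusted p = 4.74e-08). Il4, which directs IgE class switching, rose from 6.06 ± 0.14 to 11.63 ± 0.47 (SD, n = 3 each; adjusted p = 1.08e-06). Gata3, the transcription factor of the Th2 lineage, rose by 3.07 on the log2 scale (SE 0.31, adjusted p = 0.000567), from a naive level of 8.77 ± 0.75 (SD, n = 3). The naive levels of Il5, Il13 and Il4 lay under the 95th percentile of olfactory receptor genes (6.53), so that the sizes of these differences are those of intensities and not of expression.

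The 8 genes with the largest rise in intensity were Il5, Il10, Il13, Il3, Il9, Lilr4b, Mt2 and Il4, with log2 differences of 7.50, 7.03, 6.73, 6.41, 6.35, 5.93, 5.61 and 5.57. Lilr4b encodes a leukocyte receptor and Mt2 a metallothionein that binds zinc. The 8 with the largest fall in intensity were Ms4a4b, Dapl1, Atp1b1, Actn1, Itm2a, Cmah, St8sia6 and Ipcef1, with log2 differences of -4.02, -3.90, -3.65, -3.64, -3.62, -3.44, -3.42 and -2.97. Actn1 encodes an actin crosslinker, Atp1b1 a subunit of the sodium pump, and Cmah and St8sia6 act on sialic acids. All of the first 8 except Mt2 had naive means, and all of the second 8 early Th2 means, under 6.53, so that neither the sizes nor the order measure expression. All 16 genes were separated without overlap between the 3 arrays of each group. Dapl1 failed the threshold in each of the 6 fits without 1 Th2 array (early Th2 1, 2 or 3, or stable Th2 1, 2 or 3), with an adjusted p of up to 0.115.

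**Figure D1:**
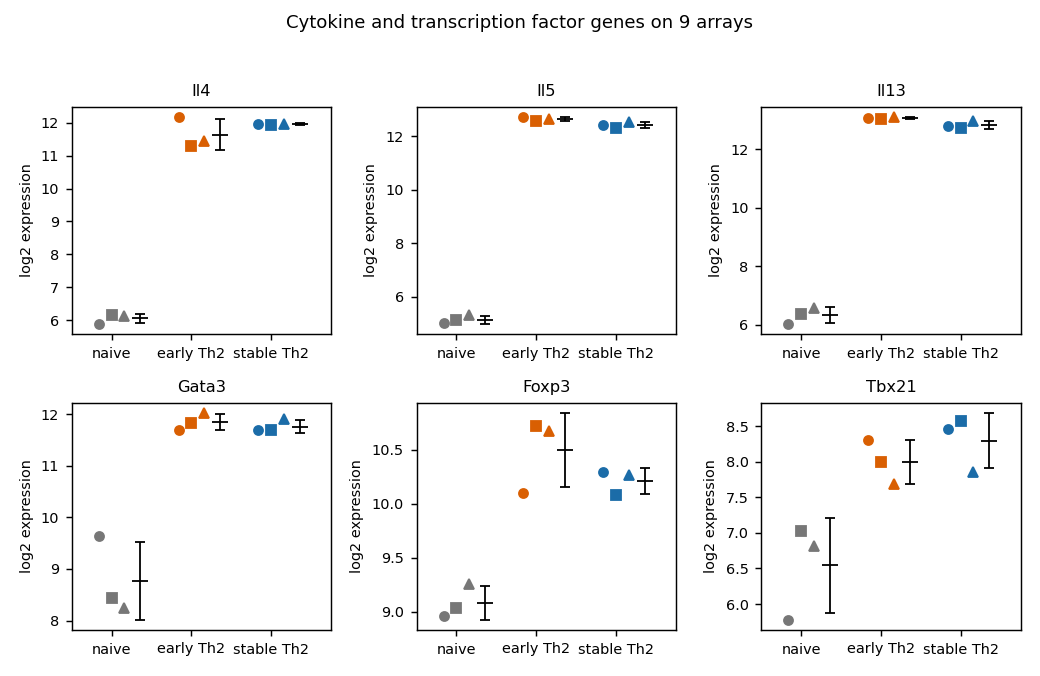
Log2 expression of Il4, Il5, Il13, Gata3, Foxp3 and Tbx21 on the 9 arrays, by group. Points are single arrays (circle, square and triangle for replicates 1, 2 and 3), and the black bar gives the mean and SD of 3 arrays. Il5 lies at 5.15 in naive cells, 12.65 in early Th2 cells and 12.43 in stable Th2 cells, as group means.

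Of the 30 measured genes of the Th2 lineage and cytokines list, 23 rose and 0 fell, with 26 higher and 1 lower when adjusted over the list alone (median log2 difference 2.80, camera adjusted p = 1.02e-42). Besides the cytokines, Ccr4 (4.59) and Ccr8 (3.97), chemokine receptors of Th2 cells, and Pparg (3.35), a nuclear receptor for lipids, rose. In the Treg list, 9 of 15 members rose and 0 fell (10 and 0 adjusted over the list alone, median 1.42, camera adjusted p = 1.28e-14), among them the inhibitory receptor gene Ctla4 (4.96) and Foxp3 (1.41), the lineage factor of regulatory T cells. In the Th17 list, 7 of 12 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.97, camera adjusted p = 7.02e-14), led by the cytokine gene Il17f (4.39) and by Ahr (2.70) and Batf (2.54), which encode transcription factors. In the Th1 and cytotoxic list, 7 of 22 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.30, camera adjusted p = 0.000957). They included Gzmb (5.05), a cytotoxic protease, Klrg1 (2.94), an inhibitory receptor, and Ifng (1.98). Tbx21, the Th1 lineage factor, rose by 1.46 with an adjusted p of 0.0382, which reached 0.141 when 1 of naive 3, early Th2 1, early Th2 2, early Th2 3, stable Th2 1 or stable Th2 2 was left out and did not pass in any of those 6 fits. In the Tfh list, 4 of 15 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.07, camera adjusted p = 0.00607, and adjusted p = 0.204 with an estimated correlation), among them the costimulatory receptor gene Icos (3.69), the cytokine gene Il21 (3.56) and Tox2 (2.34). The Th1 and cytotoxic list had 4 lower without naive 1 and 0 without naive 3 or any 1 early Th2 array, and the Tfh list 2 lower without naive 1 and 1 without naive 3.

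Lists of homing, residency, surface receptors and ILC2 markers shifted in camera as well. In the naive and lymph node homing list, 11 of 20 members fell and 0 rose (14 lower and 1 higher adjusted over the list alone, median -1.63, camera adjusted p = 3.16e-11, and adjusted p = 0.187 with an estimated correlation). In the tissue residency list, 7 of 23 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.63, camera adjusted p = 2.83e-08), led by the chemokine receptor gene Cxcr6 (5.39), by Prdm1 (3.60), which encodes the repressor Blimp-1, and by Rgs1 (2.80), and without naive 1 the count was 9 higher and 5 lower. In the costimulatory and inhibitory receptors list, 9 of 22 rose and 2 fell (11 and 2 adjusted over the list alone, median 1.35, camera adjusted p = 4.83e-10), with the inhibitory receptor genes Tigit (4.98) and Havcr2 (3.42) among the highest. In the chemokine receptors and integrins list, 8 of 28 rose and 2 fell (12 and 3 adjusted over the list alone, median 0.31, camera adjusted p = 2.59e-06), including Ccr2 (4.20). In the ILC2 list, whose 10 measured genes include 6 that other lists hold as well, 3 rose and 0 fell (5 and 0 adjusted over the list alone, median 1.03, camera adjusted p = 0.000206). The phosphatase gene Ptpn13 (2.77) was among them, and without naive 1 the count was 5. Members lower were 1 for costimulatory and inhibitory receptors without any 1 array other than naive 1, and 1 for chemokine receptors and integrins without any 1 early Th2 array. The naive and lymph node homing list had 1 higher without naive 1.

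Of 34 cell cycle genes, 15 rose and 0 fell (25 and 1 adjusted over the list alone, median 0.56, camera adjusted p = 3.07e-19, and adjusted p = 0.164 with an estimated correlation). The largest rises in intensity were those of Ccna2 (2.63), a cyclin, and Top2a (2.58), a topoisomerase of dividing cells. Next came Mki67 (2.15), a proliferation marker, and the mitotic kinesin gene Kif11 (1.91). The cell cycle list had medians of 6.41, 6.37 and 6.48 on the naive arrays, under the 95th percentile of olfactory receptor genes (6.53). The sizes and order of these rises thus need not measure expression. In the fatty acid uptake and oxidation list, 3 of 24 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.09, camera adjusted p = 0.00451, and adjusted p = 0.0624 with an estimated correlation), among them Pparg and Plin2 (3.14), which coats lipid droplets, and without naive 1 the count was 7, with 1 lower in this list and 1 in the cell cycle list. In the mast cell and basophil list, 2 of 11 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.07, camera adjusted p = 0.00328, and adjusted p = 0.271 with an estimated correlation). They were Il4, which Th2 cells make too, and Hdc (2.75), which makes histamine.

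The other 20 tested lists did not pass in camera. Members nevertheless passed singly in the TGF-beta signalling list (6 of 26 higher, 2 lower, adjusted p = 0.62), led by the integrin gene Itgb8 (3.65) and the BMP receptor gene Bmpr2 (3.29), and in the Notch signalling list (3 of 21 higher, 2 lower, adjusted p = 0.983). In the T cell receptor induced early genes list, 4 of 28 were higher, with a median of -0.10, a mean of 0.29 and an adjusted p of 0.0821. Without naive 1 this list had 6 higher and 8 lower, a median of -0.26 and the direction down in camera (adjusted p = 0.879), and it passed upward without naive 2 (adjusted p = 0.0244), naive 3 (adjusted p = 0.0149) or early Th2 1 (adjusted p = 0.0262). The survival and apoptosis list had 3 of 21 higher, Tnfsf10 (2.88), a death ligand, among them, and 1 lower (adjusted p = 0.862). The unfolded protein response and secretion list had 3 of 24 higher, Ern1 (2.21) the most, and 1 lower (adjusted p = 0.0821). It had 4 higher and 4 lower without naive 1 (median -0.17, adjusted p = 0.609), and it passed upward without naive 2 (adjusted p = 0.00208), naive 3 (adjusted p = 0.0364) or early Th2 1 (adjusted p = 0.0262). The glycolysis list had 2 of 19 higher, with Tpi1 at 1.54, and 1 lower (adjusted p = 0.0607), and the cholesterol synthesis list 2 of 18 higher, with Sc5d at 1.08 (adjusted p = 0.0534). The dissociation stress list had 1 higher and 1 lower of 21 (adjusted p = 0.901). In camera, the type I interferon response (adjusted p = 0.0875), ribosomal proteins (adjusted p = 0.0875) and microRNA machinery (adjusted p = 0.0534) lists had 0 genes past the threshold in limma, with 5, 2 and 3 genes at an unadjusted p under 0.05. Of the markers of other cells, the NK cell (adjusted p = 0.901), eosinophil (adjusted p = 0.33) and lung epithelium (adjusted p = 0.499) lists had 1 gene higher each. For the eosinophil list this was Ccr3 (0.91), which the Th2 list holds too. The B cell, macrophage and monocyte, dendritic cell, neutrophil, endothelium and stroma, and erythroid and platelet lists had 0, with 2, 2, 1, 0, 1 and 1 at an unadjusted p under 0.05. Their camera adjusted p ran from 0.33 to 0.983. The CD8 T cell list (2 genes measured) and the sex-linked list (4 genes measured) were too short to test and had 0 genes past the threshold, with 1 each at an unadjusted p under 0.05. Medians and means differed in sign for the survival and apoptosis, TGF-beta signalling, B cell and lung epithelium lists or lay against the direction of camera for Notch signalling, all among lists that did not pass. Without naive 1, members lower were 5 for TGF-beta signalling, 4 for survival and apoptosis and 3 for type I interferon response, dissociation stress had 4 higher and 3 lower, and glycolysis 4 higher and 2 lower. Without naive 2, glycolysis had 5 higher and lung epithelium 2. The NK cell list had 0 higher without any 1 array other than naive 1. Dissociation stress had 0 higher without naive 2, naive 3 or any 1 early Th2 array, 2 lower without naive 3 or stable Th2 1, and 0 lower without early Th2 2 or 3. Survival and apoptosis had 1 higher without any 1 early Th2 array, 0 lower without naive 3 or any 1 early Th2 array, and 2 lower without stable Th2 3. Notch signalling had 0 higher without early Th2 2 or 3, 1 without stable Th2 2, and 1 lower without any 1 early Th2 array. Unfolded protein response and secretion had 0 lower without early Th2 1 or 2. Cholesterol synthesis had 1 higher without naive 2, naive 3, early Th2 1 or early Th2 2. Lists with 0 members past the threshold gained 1: type I interferon response and ribosomal proteins (lower, naive 3), B cell (higher, naive 1 or early Th2 2, and lower, naive 2), dendritic cell (higher, naive 1 or early Th2 2), macrophage and monocyte (lower, naive 1) and endothelium and stroma (lower, early Th2 1). Calls in camera were gained upward for glycolysis (without naive 2 or early Th2 1) and cholesterol synthesis (naive 2 or early Th2 3). They were gained downward for type I interferon response (naive 2 or naive 3), ribosomal proteins (naive 3 or early Th2 2), microRNA machinery (naive 3, early Th2 2 or early Th2 3) and endothelium and stroma (early Th2 1).

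Over all 19937 genes, limma called 1171 between early Th2 and naive cells at an adjusted p under 0.05, 732 higher and 439 lower, and 587 of them differed at least 2-fold. The 3 arrays of each group did not overlap for 19.7% of genes, where chance gives 10%. With the surface markers of the sort, Cd44 rose by 1.93 (adjusted p = 0.000289), a difference that the sort itself sets. Cd4 had a log2 difference of 0.35 (adjusted p = 0.689) and Cd69 one of -0.51 (adjusted p = 0.683), and both passed without naive 1, with values of 0.77 for Cd4 and -1.02 for Cd69. Of the 13 list calls, 8 held with an estimated correlation. Of the called genes, 104 lay under the 95th percentile of olfactory receptor genes (6.53) in both group means, 77 of them higher. Without naive 1, 2424 genes were called, against 653 without early Th2 3 and 681 without early Th2 2, and the cell cycle list had 9 members higher without early Th2 1 or early Th2 2, while the naive and lymph node homing list had 7 lower without early Th2 1, early Th2 2, early Th2 3 or stable Th2 2. The count was 4019 with array weights, 2624 without naive 1 and stable Th2 3, a setting chosen after seeing the data, and 762 when the 6 arrays of both groups were fitted alone. The balance of directions moved too: 1206 were higher and 1218 lower without naive 1, 1308 and 1316 without naive 1 and stable Th2 3, and 1948 and 2071 with array weights.

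Stable Th2 cells were compared with the same naive cells to see which genes distinguish lung T cells of chronic inflammation. Type 2 cytokine genes again rose. Il10, which encodes a regulatory cytokine, had a level of 12.57 ± 0.12 (SD, n = 3) in stable Th2 cells and 5.05 ± 0.39 (SD, n = 3) in naive cells (adjusted p = 3.48e-07). Il5 rose to 12.43 ± 0.12 (SD, n = 3; adjusted p = 6.76e-09) and Il13 to 12.83 ± 0.13 (SD, n = 3; adjusted p = 6.37e-08), all 3 from naive levels under 6.53. Gata3 rose by 2.98 on the log2 scale (SE 0.31, adjusted p = 0.00068), to 11.76 ± 0.12 (SD, n = 3).

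The 8 genes with the largest rise in intensity were Il10, Il5, Il13, Il9, Lilr4b, Il4, Penk and Mt2, with log2 differences of 7.52, 7.27, 6.50, 6.42, 5.95, 5.89, 5.78 and 5.58. Penk encodes the precursor of the enkephalins, opioid peptides. The 8 with the largest fall in intensity were Ms4a4b, Actn1, Dapl1, Atp1b1, Itm2a, Cmah, Lef1 and St8sia6, with log2 differences of -4.23, -3.76, -3.71, -3.61, -3.56, -3.53, -3.50 and -3.42. Lef1 encodes a transcription factor of naive T cells. As before, all but Mt2 of the first 8 had naive means, and all but Lef1 of the second 8 stable Th2 means, under 6.53, so that neither the sizes nor the order measure expression. Dapl1 again failed the threshold without any 1 of the 6 Th2 arrays (early Th2 1, 2 or 3, or stable Th2 1, 2 or 3), with an adjusted p of up to 0.107.

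Of the 30 genes of the Th2 lineage and cytokines list, 21 rose and 0 fell (22 and 0 adjusted over the list alone, median 2.43, camera adjusted p = 4.87e-26), with Ccr4 at 4.56, Ccr8 at 4.18 and Pparg at 3.27. In the Treg list, 8 of 15 rose and 0 fell (11 higher and 1 lower adjusted over the list alone, median 1.21, camera adjusted p = 1.32e-06), including Ctla4 (5.28) and Foxp3 (1.13). In the Th17 list, 6 of 12 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.04, camera adjusted p = 2.26e-07), led by Ahr (3.41), Il17f (3.16) and Batf (2.30). In the Th1 and cytotoxic list, 6 of 22 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.31, camera adjusted p = 0.027, and adjusted p = 0.122 with an estimated correlation), including Gzmb (4.56), Klrg1 (2.72), Ifng (1.79) and Tbx21 (1.75). The camera call of the Th1 and cytotoxic list ended without naive 1 (adjusted p = 0.0812) or stable Th2 3 (adjusted p = 0.0553), and Tbx21 did not pass without stable Th2 1 or stable Th2 2 (adjusted p of up to 0.075). The Th1 and cytotoxic list had 4 lower without naive 1 and 0 without naive 3, stable Th2 1 or stable Th2 2. The Treg list had 1 lower without naive 1. The Tfh list had 4 of 15 higher, Icos, Il21 (3.17) and Tox2 (2.21) among them, and 1 lower, with 6 and 4 adjusted over the list alone (camera adjusted p = 0.0886), and it passed upward without naive 2 (adjusted p = 0.0422). Members lower of the Tfh list were 4 without naive 1, 2 without naive 3, and 0 without naive 2, early Th2 2, early Th2 3, stable Th2 1 or stable Th2 2.

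In the naive and lymph node homing list, 11 of 20 fell and 0 rose (15 and 0 adjusted over the list alone, median -1.81, camera adjusted p = 9.54e-11, and adjusted p = 0.189 with an estimated correlation). In the tissue residency list, 8 of 23 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 0.00064), with Cxcr6 at 5.51, Prdm1 at 3.97 and Rgs1 at 2.89. In the costimulatory and inhibitory receptors list, 9 of 22 rose, Tigit (5.25) and Havcr2 (3.43) among them, and 3 fell (13 and 4 adjusted over the list alone, median 1.20, camera adjusted p = 0.000269). In the chemokine receptors and integrins list, 9 of 28 rose, Ccr2 (4.77) among them, and 3 fell (10 and 6 adjusted over the list alone, median 0.22, camera adjusted p = 0.00386). With an estimated correlation the adjusted p was 0.122 for each of these last 3 lists. In the ILC2 list, 3 of 10 rose, Ptpn13 (2.63) among them, and 0 fell (4 and 0 adjusted over the list alone, median 0.91, camera adjusted p = 0.00076, and adjusted p = 0.0655 with an estimated correlation). Without naive 1 the ILC2 list had 6 higher, the costimulatory and inhibitory receptors list 5 lower, the tissue residency list 10 higher and 7 lower and the naive and lymph node homing list 2 higher, and the naive and lymph node homing list had 7 lower without stable Th2 1 or stable Th2 2.

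Among lists of basic cell functions, 3 shifted. Of 34 cell cycle genes, 3 rose and 0 fell (5 and 1 adjusted over the list alone, median 0.21, camera adjusted p = 0.027, and adjusted p = 0.741 with an estimated correlation): Top2a (1.37), Mki67 (0.97) and Tyms (0.67), which makes thymidylate. The count for the cell cycle list was 1 without naive 2, naive 3, early Th2 2, early Th2 3 or stable Th2 2, it was 0 without stable Th2 1 and 6 without stable Th2 3, 2 were lower without naive 1, and the camera call ended without naive 3 (adjusted p = 0.0596), stable Th2 1 (adjusted p = 0.105) or stable Th2 2 (adjusted p = 0.0576). Top2a failed in 7 of 9 fits without 1 array (all but naive 1 and stable Th2 3, adjusted p of up to 0.126), Mki67 in 6 (all but naive 1, early Th2 1 and stable Th2 3, up to 0.101) and Tyms without stable Th2 1 (0.0654). Of 22 ribosomal proteins, 3 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.38, camera adjusted p = 2.96e-06, and adjusted p = 0.14 with an estimated correlation), namely Rps19 (-0.71), Rpl8 (-0.61) and Rpl19 (-0.53). Without 1 array the count for ribosomal proteins was 6 (naive 1), 5 (stable Th2 3) or 1 (stable Th2 1). Rps19 failed in 7 of 9 such fits (all but naive 1 and stable Th2 3, adjusted p of up to 0.138) and after cyclic loess normalization (0.0557), and Rpl19 failed without naive 2 or stable Th2 1 (up to 0.0714). Of 18 genes of the microRNA machinery list, 2 fell and 0 rose (2 and 0 adjusted over the list alone, median -0.35, camera adjusted p = 0.00317, and adjusted p = 0.122 with an estimated correlation): Ago1 (-0.57), an Argonaute protein, and Dicer1 (-0.48), which cuts microRNA precursors. Neither gene passed after cyclic loess normalization, a setting chosen after seeing the data, with adjusted p of 0.0876 for Ago1 and 0.0928 for Dicer1, and the count for microRNA machinery was 4 without naive 1, 0 without naive 2 or stable Th2 1, and 1 without early Th2 1, early Th2 2, early Th2 3 or stable Th2 3. Ago1 failed in 7 of 9 fits without 1 array (all but naive 1 and stable Th2 2, adjusted p of up to 0.117). Dicer1 failed without naive 2 or stable Th2 1 (up to 0.0949). On the stable Th2 arrays the median of 1015 olfactory receptor genes was 0.34 above that on the naive arrays, and 40 of them were called.

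Markers of other cells passed singly. In the mast cell and basophil list, 3 of 11 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 0.00908, and adjusted p = 0.369 with an estimated correlation), among them Il4 and Hdc (0.95). The eosinophil list had 1 of 7 higher, Ccr3 (1.07), with 1 adjusted over the list alone (median 0.18, camera adjusted p = 0.027, and adjusted p = 0.363 with an estimated correlation), and its call ended without naive 1 (adjusted p = 0.0812) or stable Th2 1 (adjusted p = 0.0507). The lung epithelium list had 2 of 14 higher, with 2 adjusted over the list alone (median 0.11, camera adjusted p = 0.0373, and adjusted p = 0.552 with an estimated correlation), and its call ended without naive 1 (adjusted p = 0.051), naive 3 (adjusted p = 0.0759), stable Th2 1 (adjusted p = 0.0617) or stable Th2 3 (adjusted p = 0.0665). Neither call held after cyclic loess normalization, with adjusted p of 0.107 for the eosinophil list and 0.133 for the lung epithelium list, and the medians of both lists lay below the olfactory receptor shift of 0.34. Olfactory receptor genes had lower levels than both lists, so that 0.34 need not be the background shift of these lists. The NK cell, macrophage and monocyte, dendritic cell, neutrophil, endothelium and stroma, erythroid and platelet, CD8 T cell and sex-linked lists had 0 genes past the threshold in limma, with 2, 4, 4, 2, 0, 1, 1 and 0 at an unadjusted p under 0.05. The B cell list had 1 of 14 lower (camera adjusted p = 0.0565). Of the remaining lists, none of which passed in camera with all 9 arrays, TGF-beta signalling had 6 of 26 higher, Itgb8 (4.28) and Bmpr2 (3.30) among them, and 3 lower (adjusted p = 0.679). Notch signalling had 2 of 21 higher and 2 lower (adjusted p = 0.615), T cell receptor induced early genes 4 of 28 higher (adjusted p = 0.936), and survival and apoptosis 2 of 21 higher, Tnfsf10 (2.74) among them, and 2 lower (adjusted p = 0.197). Glycolysis had 1 of 19 higher, Tpi1 (1.13), and 1 lower (adjusted p = 0.53). Fatty acid uptake and oxidation had 2 of 24 higher, Plin2 (2.21) among them (adjusted p = 0.601), and cholesterol synthesis 2 of 18 higher, Sc5d (1.30) among them (adjusted p = 0.944). Type I interferon response had 1 of 22 lower (adjusted p = 0.0886), unfolded protein response and secretion 2 of 24 higher, Ern1 (1.67) among them, and 1 lower (adjusted p = 0.944), and dissociation stress 2 of 21 higher and 3 lower (adjusted p = 0.462). Among these, medians and means differed in sign for NK cell, T cell receptor induced early genes, TGF-beta signalling, Notch signalling, glycolysis, fatty acid uptake and oxidation, and cholesterol synthesis, and camera pointed down against a positive median for unfolded protein response and secretion. Without naive 1, the unfolded protein response and secretion list had 3 higher and 8 lower, a median of -0.30 and a downward call in camera (adjusted p = 0.0181), and without any other array it had 0 to 2 higher and 0 or 1 lower. The T cell receptor induced early genes list had 6 higher and 12 lower without naive 1 (median -0.38, adjusted p = 0.173), and it passed downward without naive 1 and stable Th2 3 (adjusted p = 0.00746). Without naive 1, fatty acid uptake and oxidation had 5 higher and 3 lower, Notch signalling 4 and 4, dissociation stress 4 and 5, glycolysis 5 lower, TGF-beta signalling 5 lower, survival and apoptosis 4 lower and B cell 2 higher. Without stable Th2 3, B cell and dendritic cell had 2 higher each, neutrophil 1 higher and T cell receptor induced early genes 2 lower. The B cell list had 0 lower without any 1 array other than naive 2. Type I interferon response had 2 lower without naive 1 or naive 3 and 0 without any other array except stable Th2 3. TGF-beta signalling had 1 lower without stable Th2 1. Survival and apoptosis had 1 lower without naive 3 and 0 without stable Th2 1 or 2. It had 1 higher without naive 3, early Th2 2, early Th2 3 or stable Th2 2. Notch signalling had 1 higher without naive 2, naive 3 or early Th2 1, 0 higher without early Th2 2 or 3 or any 1 stable Th2 array, and 1 lower without early Th2 2 or 3 or stable Th2 1 or 2. Dissociation stress had 1 higher without naive 3, stable Th2 1 or stable Th2 3 and 0 without naive 2, early Th2 1, 2 or 3, or stable Th2 2. It had 1 lower without naive 2 or early Th2 2 or 3 and 0 without stable Th2 1 or 2. Glycolysis had 2 lower without naive 3, 2 higher without early Th2 3 and 0 higher without stable Th2 1. Cholesterol synthesis had 1 higher without naive 3, early Th2 2, stable Th2 1 or stable Th2 2. The lung epithelium list had 1 higher without naive 2, stable Th2 1 or stable Th2 2. The macrophage and monocyte list gained 1 lower without naive 1, dendritic cell 1 higher without naive 1 or early Th2 2, and B cell 1 higher without early Th2 2. Calls in camera were gained downward for type I interferon response (without naive 2 or naive 3) and upward for B cell (naive 3, early Th2 2 or stable Th2 2) and neutrophil (stable Th2 2). Tpi1 did not pass without stable Th2 1 (adjusted p = 0.0585), nor Ern1 without early Th2 2, early Th2 3 or stable Th2 1 (adjusted p of up to 0.0644).

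Over all genes, limma called 1571 between stable Th2 and naive cells, 734 higher and 837 lower, and 606 of them differed at least 2-fold. The arrays of both groups did not overlap for 27.9% of genes, where chance gives 10%. The balance of directions moved with the scaling: 800 were higher and 599 lower after quantile normalization, and 812 and 599 after cyclic loess normalization. It was 1164 and 2274 without naive 1, 422 and 312 without stable Th2 1, and 1200 and 857 without stable Th2 3. Among the markers of the sort, Cd44 rose by 1.89 (adjusted p = 0.000334). Cd69 had a log2 difference of -1.09 (adjusted p = 0.158), which passed without naive 1 at -1.61, and Cd4 one of -0.19 (adjusted p = 0.698), which was 0.23 without naive 1. Of the 15 list calls, 3 held with an estimated correlation, those of the Th2 lineage and cytokines, Th17 and Treg lists. Of the called genes, 173 lay under 6.53 in both group means, 143 of them higher. Without 1 array, 3438 genes were called (naive 1), 1041 (naive 2), 1007 (early Th2 3), 734 (stable Th2 1) or 833 (stable Th2 2). The count was 4675 with array weights, 4665 without naive 1 and stable Th2 3, and 686 when the 6 arrays of both groups were fitted alone.

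Both Th2 groups shared much of their difference from naive cells. Of the genes called against naive cells, 520 were higher in both Th2 groups and 398 lower in both, and 0 were called in opposite directions. Il4, Il5, Il9, Il10, Il13, Gata3, Ctla4 and Cxcr6 were among the genes higher in both, and Lef1, Actn1, Cmah and Ms4a4b among those lower in both. Both comparisons use the same 3 naive arrays, so that some overlap follows from the design. In 20 simulations of unchanged groups that share the naive arrays, the mean overlap was 5.4 genes higher and 5.85 lower, and independent lists of these sizes would share 26.9 and 18.4. Each simulation too had 0 genes called in opposite directions. Unchanged groups give few calls and independent lists share no arrays, so that neither count measures the overlap that shared naive arrays bring here. Across genes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.878 against 0.782 simulated, and a covariance of 0.214 against 0.0392 simulated. The share of all genes with the same sign in both comparisons went the other way. It was 66.6% against 70.3% simulated (69.7% to 70.8%). The overlap of calls against naive, 918 genes in all, was 1959 without naive 1, 572 without early Th2 2, 544 without early Th2 3, 600 without stable Th2 1 and 606 without stable Th2 2. It was 2433 with array weights, 2078 without naive 1 and stable Th2 3, and 510 when 6 arrays were fitted at a time.

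Stable Th2 cells were compared with early Th2 cells to see what differs between chronic and acute inflammation in cells of one sorted type and tissue. Few genes passed the test, and the cytokine genes of the Th2 lineage were not among them. Hdc, the enzyme that makes histamine, had a level of 9.33 ± 0.29 (SD, n = 3) in early Th2 cells and 7.54 ± 0.24 (SD, n = 3) in stable Th2 cells, a log2 difference of -1.80 (SE 0.17). Grp, the precursor of gastrin-releasing peptide, fell by 1.55 (SE 0.16), from 8.81 ± 0.06 to 7.25 ± 0.29 (SD, n = 3 each). Foxb1, a forkhead transcription factor, rose by 1.33 (SE 0.12), from 6.75 ± 0.06 to 8.09 ± 0.19 (SD, n = 3 each), and Arnt2, a partner of bHLH-PAS transcription factors, rose by 1.07 (SE 0.11), from 8.10 ± 0.02 to 9.17 ± 0.12 (SD, n = 3 each).

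Shtn1, known for its role in axon growth, rose by 0.98 (SE 0.10), from 9.06 ± 0.10 to 10.04 ± 0.16 (SD, n = 3 each), and Med27, a subunit of the Mediator complex, fell by 0.77 (SE 0.08), from 9.23 ± 0.07 to 8.46 ± 0.09 (SD, n = 3 each). Med27 had an adjusted p of 0.0314, and Hdc, Grp, Foxb1, Arnt2 and Shtn1 had 0.0235 each. These 6 genes, 3 higher and 3 lower, were all that limma called, while 2962 genes had an unadjusted p under 0.05. For all 6, the 3 arrays of each group were separated without overlap, which held for 22.7% of all genes, where chance gives 10%. The probe sets are 10487238 for Hdc, 10456353 for Grp, 10594754 for Foxb1, 10565292 for Arnt2, 10468762 for Shtn1 and 10470696 for Med27. Without 1 array, limma called 0 genes (naive 3, early Th2 1, early Th2 2, early Th2 3 or stable Th2 2), 2 (stable Th2 1), 4 (naive 2), 11 (stable Th2 3) or 12 (naive 1). The split was 1 higher and 5 lower after median centring, 2 genes were called when the 6 arrays were fitted alone, 1087 without naive 1 and stable Th2 3 and 6721 with array weights, and both of these larger sets held all 6 genes. Leaving out naive 1 and stable Th2 3 was chosen after the data were seen, so that the set of 1087 is no independent support. Trended and robust moderation called 3 genes, all among the 6 (Foxb1, Grp and Hdc), and a test of all probe sets called 1. With the replicate number as a block, limma called 0 genes. Med27 did not pass after quantile (adjusted p = 0.135) or cyclic loess normalization (adjusted p = 0.169), nor Arnt2 and Shtn1 after median centring (adjusted p = 0.0529 each).

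**Figure D2:**
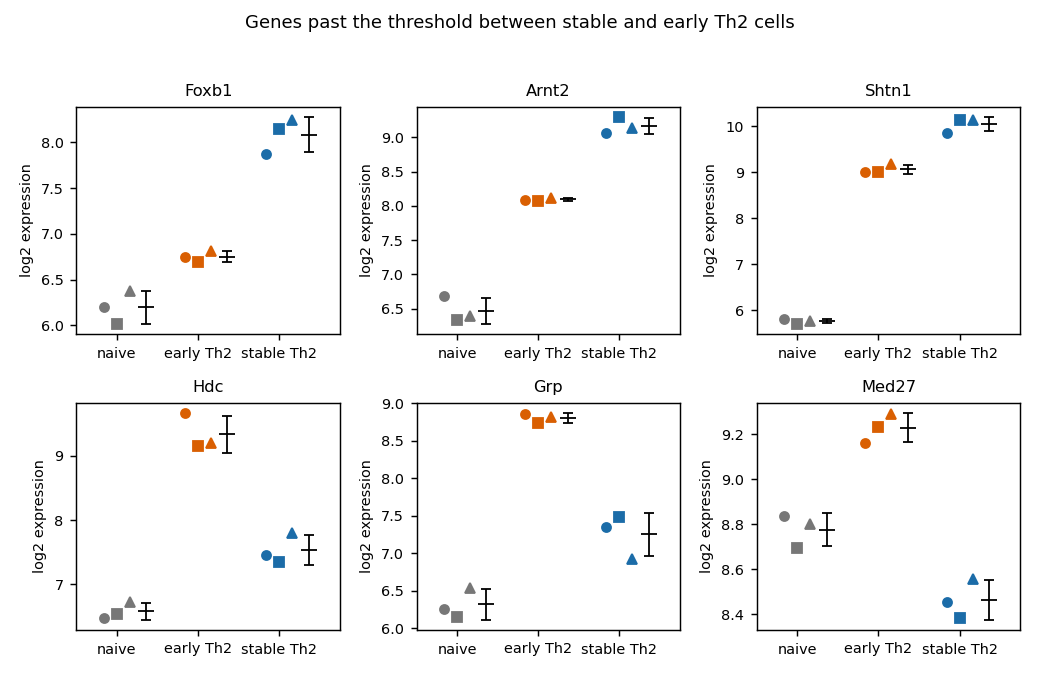
Log2 expression of Foxb1, Arnt2, Shtn1, Hdc, Grp and Med27 on the 9 arrays, by group. Points are single arrays (circle, square and triangle for replicates 1, 2 and 3), and the black bar gives the mean and SD of 3 arrays. Hdc has a group mean of 6.58 in naive cells, 9.33 in early Th2 cells and 7.54 in stable Th2 cells.

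The lineage genes had small differences between the stages. Il4 differed by 0.32 (adjusted p = 0.437), Il5 by -0.22 (adjusted p = 0.343), Il13 by -0.23 (adjusted p = 0.415), Gata3 by -0.09 (adjusted p = 0.89), Foxp3 by -0.29 (adjusted p = 0.414) and Tbx21 by 0.30 (adjusted p = 0.643), and none passed the test. With array weights, where 6721 genes were called, all of these except Gata3 passed. The value of Gata3 was 0.01 after cyclic loess normalization. Il3 (-2.02, adjusted p = 0.357), Il17f (-1.23, adjusted p = 0.322), Il17a (-1.08, adjusted p = 0.322) and Cd40lg (-1.05, adjusted p = 0.337) had lower values in stable Th2 cells without passing. These 4 values were -1.23, -0.78, -0.67 and -0.72 without stable Th2 2, and -3.01, -1.70, -1.62 and -1.58 without stable Th2 3. All 4 genes passed with array weights (adjusted p of up to 0.0162) and without naive 1 and stable Th2 3 (adjusted p of 0.0169, 0.0235, 0.0215 and 0.0076). Ccr1 (1.02, adjusted p = 0.301), Itgb8 (0.62, adjusted p = 0.301) and Ccr2 (0.57, adjusted p = 0.301) had higher values without passing. All 3 passed with array weights and without naive 1 and stable Th2 3 (adjusted p of 0.0398, 0.0467 and 0.029), and Itgb8 passed after cyclic loess normalization too (adjusted p = 0.0442). Cd4 differed by -0.54 (adjusted p = 0.392), Cd69 by -0.59 (adjusted p = 0.493) and Cd44 by -0.04 (adjusted p = 0.906), the last being 0.10 after cyclic loess normalization. Cd4 and Cd69 passed with array weights and without naive 1 and stable Th2 3 (adjusted p of 0.0235 and 0.0338). Array weights called 6721 of 19937 genes, and the fit without naive 1 and stable Th2 3 called 1087. Stable Th2 3, which correlated more with early Th2 3 than with the other stable arrays, was left out after the data were seen. Leaving it out can widen the difference between the stages, so that passing there is no independent support for these genes.

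In camera at the preset correlation, lists shifted whose members did not pass singly over all genes. All 34 cell cycle genes had lower values in stable than in early Th2 cells (median -0.44, camera adjusted p = 3.91e-18, and adjusted p = 0.44 with an estimated correlation), with Kif11 at -1.43 and Ccna2 at -1.35. Of these genes, 0 passed over all genes in limma, 21 had an unadjusted p under 0.05, and 16 were lower and 0 higher adjusted over the list alone. The glycolysis list had a median of -0.34 (camera adjusted p = 0.000259), with Pfkp at -0.57, and the ribosomal proteins list one of -0.23 (camera adjusted p = 1.86e-05), with Rpl7 at -0.48. For glycolysis 0 genes passed and for ribosomal proteins 1 was lower adjusted over the list alone, with 3 and 4 at an unadjusted p under 0.05. Both lists had an adjusted p of 0.44 with an estimated correlation. These 3 lists remained past the threshold in camera after cyclic loess normalization (adjusted p = 6.14e-20 for cell cycle, 0.00394 for glycolysis and 0.0208 for ribosomal proteins). Kif11 and Rpl7 passed singly with array weights and without naive 1 and stable Th2 3 (adjusted p of 0.0203 and 0.0239), and Ccna2 and Pfkp with array weights alone. As for the genes above, passing in these settings is no independent support.

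Another 5 lists passed in camera and did not after cyclic loess normalization. The fatty acid uptake and oxidation list had a median of -0.12 (camera adjusted p = 0.0203, then 0.372). Its only member past the threshold adjusted over the list alone was Plin2 at -0.93 (limma adjusted p over all genes = 0.124). For Plin2 it was 0.0239 without naive 1 and stable Th2 3, a setting chosen after seeing the data. The survival and apoptosis list had a median of -0.14 (camera adjusted p = 0.0365, then 0.532), and the unfolded protein response and secretion list one of -0.08 (camera adjusted p = 0.0405, then 0.917), which was 0.02 after that scaling. The B cell list had a median of 0.19 (camera adjusted p = 0.0365, then 0.32) and the neutrophil list one of 0.18 (camera adjusted p = 0.0365, then 0.451). With an estimated correlation the adjusted p was 0.44 for fatty acid uptake and oxidation and 0.563 for the other 4 lists. Olfactory receptor genes differed by a median of 0.33 between the same arrays, and differences between the stages fell with mean level across genes (Spearman rho -0.572, and -0.190 after cyclic loess normalization). In fry, which tests a list without comparing it with other genes, 0 of 33 lists passed, against 15 for early minus naive and 18 for stable minus naive. Leaving out an array ended camera calls among these 5 lists for survival and apoptosis (early Th2 2, early Th2 3, stable Th2 1 or stable Th2 2, adjusted p of 0.17, 0.0742, 0.194 and 0.0575), for unfolded protein response and secretion (naive 2, early Th2 2, early Th2 3 or stable Th2 1, adjusted p of 0.0503, 0.103, 0.0742 and 0.103), for B cell (early Th2 2 or stable Th2 1, adjusted p of 0.125 and 0.103) and for neutrophil (early Th2 2, stable Th2 1 or stable Th2 3, adjusted p of 0.103, 0.103 and 0.0539).

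**Figure D3:**
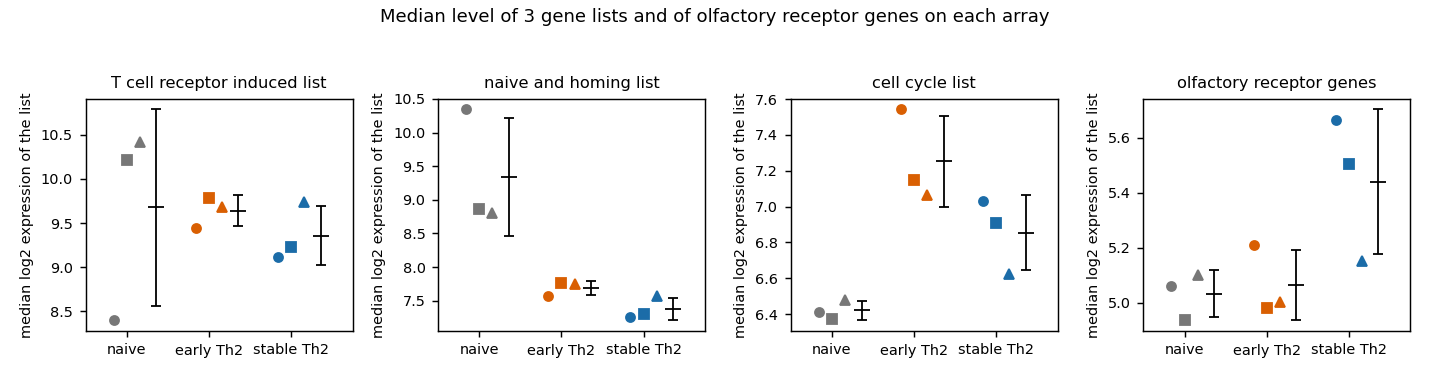
Median log2 expression of the T cell receptor induced early genes, the naive and lymph node homing, and the cell cycle lists and of 1015 olfactory receptor genes on each of the 9 arrays. Points are single arrays (circle, square and triangle for replicates 1, 2 and 3), and the black bar gives the mean and SD of 3 arrays. The cell cycle median is 7.54, 7.15 and 7.07 on the early Th2 arrays and 7.03, 6.91 and 6.62 on the stable Th2 arrays.

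The other 25 tested lists had no shift past the threshold in camera between the stages. The Th2 lineage and cytokines list had a median of -0.03 (adjusted p = 0.468), Th1 and cytotoxic 0.01 (adjusted p = 0.309), Th17 -0.09 (adjusted p = 0.187), Treg -0.01 (adjusted p = 0.184) and Tfh 0.02 (adjusted p = 0.272). The first of these was 0.07 after cyclic loess normalization, Treg was 0.08, and Th1 and cytotoxic was -0.08. The medians of the Tfh, NK cell, mast cell and basophil, type I interferon response, dissociation stress, chemokine receptors and integrins, and erythroid and platelet lists changed sign in at least 1 of 3 scalings too. Naive and lymph node homing (-0.07, adjusted p = 0.161), tissue residency (-0.02, adjusted p = 0.468), costimulatory and inhibitory receptors (-0.09, adjusted p = 0.232), chemokine receptors and integrins (0.03, adjusted p = 0.696) and T cell receptor induced early genes (-0.14, adjusted p = 0.0839) did not pass. Nor did TGF-beta signalling (0.09, adjusted p = 0.499), Notch signalling (-0.04, adjusted p = 0.331), type I interferon response (0.04, adjusted p = 0.837), cholesterol synthesis (-0.12, adjusted p = 0.0856), microRNA machinery (-0.15, adjusted p = 0.0885) and dissociation stress (-0.03, adjusted p = 0.452). Among 10000 level-matched random lists each, TGF-beta signalling lay at percentile 99.95, dissociation stress at 97.97, NK cell at 2.28 and the 3 sort markers, too few for camera, at 0.39 (median -0.54), all outside the middle 95%. Among markers of other cells, the macrophage and monocyte (0.14, adjusted p = 0.0513), lung epithelium (0.15, adjusted p = 0.0513), eosinophil (0.22, adjusted p = 0.0527), dendritic cell (0.15, adjusted p = 0.176), endothelium and stroma (0.14, adjusted p = 0.0864), erythroid and platelet (0.08, adjusted p = 0.468), NK cell (0.03, adjusted p = 0.837) and ILC2 (0.09, adjusted p = 0.837) lists lay below the olfactory receptor shift of 0.33. All of these lists except NK cell had higher levels than olfactory receptor genes, so that 0.33 need not be their background shift. Against level-matched random lists, ILC2 lay at percentile 94.96, eosinophil at 93.35, endothelium and stroma at 91.27 and lung epithelium at 86.93. Dendritic cell lay at 82.7, macrophage and monocyte at 82.13 and erythroid and platelet at 34.83, all inside the middle 95%. The mast cell and basophil list had a median of 0.05, a mean of -0.06 and an adjusted p of 0.837, with Hdc as its 1 lower member, which did not pass without naive 3, any 1 early Th2 array, stable Th2 1 or stable Th2 2. Means lay against the medians in sign for Th1 and cytotoxic and Tfh too, and camera pointed down against positive medians for these, type I interferon response, and chemokine receptors and integrins. Calls in camera were gained downward for T cell receptor induced early genes and dissociation stress (without stable Th2 3), cholesterol synthesis (early Th2 3 or stable Th2 2) and microRNA machinery (early Th2 1 or stable Th2 2). They were gained upward for eosinophil and lung epithelium (early Th2 1 or stable Th2 2), endothelium and stroma (early Th2 1) and macrophage and monocyte (stable Th2 2).

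The 6 genes called between the stages were placed against their change from naive to early Th2 cells. Foxb1, Arnt2 and Shtn1 moved further in the direction they had taken from naive to early Th2 cells, and Hdc, Grp and Med27 moved back. The share moving back was 50% (3 of 6 genes, 95% exact Clopper-Pearson interval 11.8% to 88.2%, counting error only). Because the early Th2 arrays enter both differences with opposite sign, simulated unchanged groups gave 63.6% of all genes with opposite signs (63.2% to 64.0% in 20 simulations). The observed share of all genes was 57.2%. Across genes, which are not independent replicates, both differences had a Pearson correlation of -0.115 against -0.278 simulated (-0.296 to -0.254). Their covariance was -0.0135 against -0.00902 simulated (-0.00964 to -0.0083). The correlation was thus weaker and the covariance stronger than in the simulations, so that no conclusion is drawn from them. The 6 genes were selected by the test, and their share was not compared with that of all genes.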

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

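Chosen only after the results were seen were the tests of naive replicate 1, of B cells or neutrophils, of early Th2 replicate 1 and of mast cells or basophils, and the division of 8 lists into 3 and 5, while the level-matched test of those lists and the splits of the arrays were set beforehand.

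The difference from naive cells itself differed between early and stable Th2 cells for 6 genes, by the test of stable minus early Th2 cells. The log2 differences were -1.80 for Hdc, -1.55 for Grp, 1.33 for Foxb1, 1.07 for Arnt2, 0.98 for Shtn1 and -0.77 for Med27. Each had the same direction for all 9 pairs of an early and a stable array, which follows from the separation without overlap given above.

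Naive replicate 1 lay apart from naive replicates 2 and 3, with 8 lists outside the middle 95% of 10000 level-matched random lists: T cell receptor induced early genes (-1.18 against the mean of the other two), unfolded protein response and secretion (-0.85), costimulatory and inhibitory receptors (-0.52) and Tfh (-0.32) were lower, and naive and lymph node homing (1.33), type I interferon response (0.53), dissociation stress (0.23) and chemokine receptors and integrins (0.17) higher. A candidate explanation is weaker activation of that sample: the first of these lists, seen to be low before this test, lay at percentile 0, and whether it would bring the other 7 shifts was not tested. Another is cells of another type, and against it the highest median of any list of other cells was 0.4125, for the CD8 T cell list with 2 genes. An array-wide shift in intensity is argued against by the median of the activation list, which was -1.021 after cyclic loess normalization. No biological explanation from the design was tested, since it names none within a group, and the cause stays open.

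Between stable and early Th2 cells, 8 lists shifted in camera. An array-wide shift in intensity would move a list like random genes of its level, and 3 of 3 lists (cell cycle, glycolysis and ribosomal proteins) lay outside the middle 95% of level-matched random lists, whereas 0 of the other 5 did, so that such a shift may account for those 5. For B cells or neutrophils in the stable samples, the level of their abundant transcripts was examined, a check that is weak. The highest median of these transcripts on a stable array was 6.28, under the background level of 6.53. The median of all probe sets on the stable arrays, 6.42 to 6.48, lay under 6.53 as well. Olfactory receptor medians on these arrays, 5.15 to 5.67, were lower than 6.28. Their median difference of 0.1691 lay below that of olfactory receptor genes (0.33). That median pools both cell types, and brighter genes need not share the olfactory shift, so that such cells cannot be excluded. In the B cell list, 11 of 14 members had a positive difference, with Ighm at 0.535 and a mean level of 7.32. Early Th2 replicate 1 alone is argued against for the cell cycle list by a median of -0.3031 without that array. For the 3 lists, the stage of inflammation stays open as an untested explanation, since day and stage change together and no list held with an estimated correlation.

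Hdc was higher in early Th2 cells than in stable Th2 and naive cells. Mast cells or basophils in the early samples could bring it, and would bring their other transcripts as well. Against this, the other 9 measured members of their list, Il4 left aside, had a median early minus naive difference of 0.05863. Their highest median on an early array was 5.39, under the background level of 6.53. It also lay under the median of all probe sets on the early arrays, 6.34 to 6.40. The stage of inflammation, which goes with the day, stays open as an untested explanation.

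For each comparison, 3 arrays against 3 make 10 splits, too few for a share under 0.05. Early Th2 minus naive gave 1171 genes in the real split and at most 0 in the others, so that 1 split of the 10 gave as many, and 13 lists against at most 13, with 3 splits giving as many. Stable Th2 minus naive gave 1571 genes and at most 0 in the others (1 split), and 15 lists against at most 15 (2 splits). Stable Th2 minus early Th2 gave 6 genes and at most 5 in the others (1 split), and 8 lists against at most 11 (4 splits). The split with 5 genes set early Th2 1, stable Th2 1 and stable Th2 2 against early Th2 2, early Th2 3 and stable Th2 3. That split followed the background of the arrays. Olfactory receptor medians were 5.21, 5.67 and 5.51 on the first 3 arrays named, and at most 5.15 on the other 3. On the second principal component, the first 3 lay between 3.4 and 18.3, and the other 3 between -13.3 and -0.27. The samples thus hold an order besides the groups, and whether it gave the 5 genes was not tested.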

How the results depend on the processing

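Cyclic loess normalization and leaving out both naive 1 and stable Th2 3 were chosen after the results were seen, and the other alternatives before. None of the called genes changed sign in any setting, with all probe sets not compared. The 9 fits without 1 array each gave 653 to 2424 genes for early Th2 minus naive, 734 to 3438 for stable Th2 minus naive and 0 to 12 for stable minus early Th2. They gave 13 to 18, 12 to 17 and 4 to 12 shifted lists, an overlap of 544 to 1959 genes, and 0 to 72.7% of genes moving back toward the naive level. That share has no value where 0 genes were called: with the replicate block and without naive 3, early Th2 1, early Th2 2, early Th2 3 or stable Th2 2. In fits without an array, 1 group has 2 arrays and takes its spread from all groups.

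Among other settings, array weights gave 4019, 4675 and 6721 genes for early minus naive, stable minus naive and stable minus early Th2, and 2433 for the overlap of calls against naive. The weight was 0.165 for naive 1 and 8.23 for early Th2 3, and the cause was not tested. Without naive 1 and stable Th2 3 the values were 2624, 4665, 1087 and 2078, and the cause was not tested. With only the 2 groups compared, and thus fewer arrays, they were 762, 686, 2 and 510, and 0% of genes moved back. A 2-fold threshold left 587 genes of early minus naive and 606 of stable minus naive. For stable minus early Th2, all probe sets gave 1 gene, trended and robust moderation 3 and the replicate block 0 (limma, 3554 at an unadjusted p under 0.05). For the block, early and stable minus naive gave 1261 and 1844 genes. Deviations from the group means correlated above 0.1 in 6 of 9 pairs of arrays with one replicate number (-0.085 to 0.572). Of 18 best matches 10 were with the own number, where chance gives 1 in 3 for a single match. The matches reuse the same arrays, so that they are not independent. Early Th2 1 and stable Th2 1, the pair with the highest correlation, also had the highest olfactory receptor medians of their groups (5.21 and 5.67). Whether the numbers pair the samples is thus not decided. Between early and stable Th2 cells, the correlation was 0.572 for replicate 1, -0.012 for replicate 2 and 0.403 for replicate 3. With the estimated correlation, 8, 3 and 0 lists shifted. Fry gave 15, 18 and 0 lists. For early minus naive, TGF-beta signalling (fry adjusted p = 0.000559) and microRNA machinery (0.0229) passed there but not in camera. For stable minus naive, TGF-beta signalling (0.000133), Tfh (0.000465), fatty acid uptake and oxidation (0.00307) and erythroid and platelet (0.047) did so. The cell cycle list of that comparison passed in camera but not in fry (0.251). For stable minus early Th2, quantile and cyclic loess normalization gave 3 lists each, and genes above the median level 5. Where no reason is given, the cause was not tested.

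Reversed values were those of genes that did not pass. The log2 difference of Cd44, stable Th2 minus early Th2, was 0.063 after quantile and 0.10 after cyclic loess normalization, and -0.19 to 0.081 without 1 array. Gata3 (stable minus early Th2) was 0.012 after cyclic loess normalization. Cd4 (stable minus naive) was 0.15 with array weights, 0.20 without naive 1 and stable Th2 3, and -0.43 to 0.23 without 1 array. The cause was not tested. Of the other results, list counts and single genes, 2159 values held, 137 moved, 38 newly passed and 43 no longer passed outside the 9 fits without 1 array. In those 9 fits, 1664 held, 188 moved, 3 newly passed and 94 no longer passed. Signal over background limits the dimmest genes, as 104 and 173 calls against naive cells lay under the background level of 6.53 in both groups.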

Other observations

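No test was added for this part, and the genes in it were chosen after the results were seen. Hairpin genes of microRNAs are on the arrays, and 300 were tested. Mir31 rose by 0.96 in early Th2 cells against naive cells (adjusted p = 0.0209), and 2 others fell, Mir505 and Mir7-1. In stable Th2 cells 12 were higher and 1, Mir701, lower than in naive cells, on arrays where background was higher too. Between stable and early Th2 cells limma called 0, with 61 at an unadjusted p under 0.05. Mir155, the hairpin gene of a microRNA of activated lymphocytes, had a level of 6.29 in naive replicate 1 and between 9.45 and 10.39 on the other 8 arrays.

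Kcnma1, a potassium channel gene, had levels of 11.81 in early Th2 replicate 2 and 11.96 in stable Th2 replicate 3 and between 5.26 and 7.88 on the other 7 arrays. Bex4 had a level of 7.17 in stable Th2 replicate 1 and between 2.97 and 4.30 on the other 8. Aqp9, a channel for water and glycerol, lay near the threshold between the stages (log2 difference -0.79, adjusted p = 0.0639). Stable Th2 replicate 3 correlated with early Th2 replicate 3 at 0.991 across genes, and with stable Th2 replicates 1 and 2 at 0.980 and 0.985.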
